A study of Homo sapiens with 2 samples.

How the data were processed

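Mature microRNAs (miRNAs) were profiled on 2 single-colour arrays, 1 from Huh7 cells labelled as control and 1 from Huh7 cells exposed to Y27632. Huh7 is an established human hepatocellular carcinoma line. Y27632 is a small-molecule kinase inhibitor, whose target is not reported here. Per the labels' protocols, cells were grown in Dulbecco's medium with fetal bovine serum, total RNA was isolated with ISOGEN, and the RNA was labelled with the fluorescent dye Hy5 by an Exiqon miRCURY labelling kit. The control's group came from its title and the series design, since the treatment text is attached to both samples. That title states no vehicle and no time of harvest. A difference in either could not be told apart from an effect of Y27632.

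The deposited values are array intensities on a linear scale, as judged from their range, with 1 value per probe and array given to 1 decimal. The authors' background correction, normalization, detection limit and software are not given in the sources used here, so neither the scale nor the centring of the values is known. A linear scale is an inference, because values run from 2.3 to 45829.6 with a long upper tail. Cells without a value are called not listed below, because no source used here says whether they mark low signal or a rejected spot. Scanner files were not used here, so spot replicates, background and saturation could not be examined. The unit is intensity, which gives no count of molecules, and the number of arrays limits the precision.

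Rows carry miRBase mature-sequence accessions (MIMAT numbers), and the table does not pair them with miRNA names. The gene table used as reference (GRCh38.p14) held 0 lines with such an accession. No miRNA was therefore named, located in the genome or assigned to a family. The 19 miRNA lists fixed before the data were examined (families, clusters and cell type markers) were not evaluated for the same reason, and because unpaired accessions mean little to a reader, at most 2 accessions are printed in each direction. Of the 1001 rows, 5 carry several accessions. None of those 5 was listed on both arrays.

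For each probe listed on both arrays, the log2 ratio of the Y27632 array over the control array was computed from the deposited intensities with no further normalization and no pseudocount. With 1 array per condition there is no replicate error. No test was made, no p-value is given, and differences describe these 2 arrays, not the conditions. The rules were set before the data were examined. A probe counted as higher or lower at a difference of at least 2-fold (log2 ratio of at least 1 in size), within the brighter 50% of probes by mean log2 intensity. Probes to be named were up to 12 in each direction that passed, or the 5 largest where none passed, and the 5 brightest on the control array. As a scale for each ratio, its distance from the median of the 100 probes nearest in brightness was divided by their robust SD (the scaled median absolute deviation). That spread mixes technical noise and any treatment effect, and this measure was added after seeing the data.

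Processing choices varied were median centring, quantile normalization, a lowess correction (fraction 0.4), a pseudocount of 3.25 (the mean over both arrays of the 10th percentile), no filter on dim probes, the brightest 25% of probes, a 1.5-fold limit, and missing values set to the lowest value listed on that array. The rule was tested on simulated data built from the 519 measured mean levels and local spreads, in 20 runs with 40 of the 260 probes of the brighter 50% changed. It recovered 98.6% of 3-fold changes and 99.9% of 4-fold changes, and passed 0.0909% and 0.136% of unchanged probes of that set in the respective runs. The simulation holds no bias between arrays. Its noise was normal at the local robust SD, so it lacks heavier tails, and the share of unchanged probes passing may be understated. In the brightest 25% the SD of the measured log2 ratios was 0.21 and the robust SD 0.16. Changes of 2-fold, the size at the limit, were not simulated. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.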

Results

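Mature miRNA levels were measured in control Huh7 hepatocellular carcinoma cells and after 12 hours in 10 µM Y27632, a small-molecule kinase inhibitor. Each condition was represented by 1 array, so no value below has a replicate error. The table covered 1001 probes. The control array listed an intensity for 619 of them (61.8%) and the Y27632 array for 614 (61.3%). Both arrays listed 519 probes, the control array alone listed 100, the Y27632 array alone listed 95, and 287 were listed on neither.

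The summed array signal came mostly from a few probes on both arrays. Median listed intensity was 6.0 on the control array and 6.1 on the Y27632 array, with quartiles of 3.6 and 17.7 in the control and 4.0 and 17.95 after treatment. The brightest probe was the same on both and carried 38.5% of the summed intensity in the control (45829.6) and 34.6% after treatment (43198.2). The 10 brightest probes carried 78.7% and 80.3% of the sums. Intensities of different probes do not rank the miRNAs by abundance. An intensity above 100 was reached by 62 probes on each array, of which 59 were shared, and an intensity above 1000 by 11 control and 10 Y27632 probes.

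The 2 arrays had similar orders of probe intensity, to which brightness that belongs to each probe contributes on any pair of arrays. All 10 of the brightest control probes were among the 10 brightest Y27632 probes, and 49 of the 50 brightest were shared. Across the 519 probes listed on both arrays, Pearson's r of log2 intensity was 0.986 and Spearman's rho was 0.923. Among the 260 probes of the brighter 50% these were 0.993 and 0.971, and among the 259 dimmer probes 0.430 and 0.435. These correlations run across probes of 2 arrays, and probes are not independent replicates.

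The comparison of treated with control cells asked which mature miRNAs differ after this treatment. Of the 260 miRNA probes of the brighter 50%, whose geometric mean intensity was at least 7.57, 0 were at least 2-fold higher after Y27632 and 1 was at least 2-fold lower. At a 1.5-fold limit, 3 were higher and 6 were lower, so 251 probes (96.5%) lay within 1.5-fold. The median log2 ratio in this set was −0.03, with quartiles of −0.22 and 0.12. Over all 519 probes the median log2 ratio was 0.00 (SD across probes 0.39), with 252 probes above 0, 254 below and 13 at 0. No test was possible with 1 array per condition.

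The probe at least 2-fold lower was MIMAT0000435. Its intensity was 65.3 in control cells and 32.6 after Y27632, a log2 ratio of −1.002. It lay 4.50 robust SDs below the median of the 100 probes nearest in brightness. The log2 ratio was −0.95 after quantile normalization, −0.96 after a lowess correction and −0.94 with a pseudocount, each short of the 2-fold limit. The control rank of this probe was 82 and its rank after treatment 111. Since it passed, the fixed rule picked no further falls. Among the same brighter probes, the falls ranked 2 and 3 by size had log2 ratios of −0.88 and −0.84. Their intensities were 14.9 and 15.8 in the control, and 8.1 and 8.8 after Y27632. They lay 2.54 and 2.48 robust SDs below probes of like brightness. Both were larger in size than the largest rise, at 0.76. The falls ranked 4 and 5 were at −0.69 and −0.63.

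No probe of the brighter 50% reached the limit in the other direction, and the 5 largest ratios had log2 values between 0.55 and 0.76. The largest belonged to MIMAT0007892, at 17.8 in the control and 30.2 after Y27632 (log2 ratio 0.76, 2.96 robust SDs above probes of like brightness). The much brighter probe MIMAT0005947 read 5564.3 in the control and 8474.8 after treatment. Its log2 ratio was 0.61, but 0.26 after quantile normalization. It lay 4.48 robust SDs above the 100 probes nearest in brightness, of which 3 were brighter and the dimmest was at 40.7. A probe at 91.5 in the control and 133.6 after treatment (log2 ratio 0.55) lay 3.58 robust SDs above its neighbours. The rest of the 5 were dimmer and lay closer to their neighbours. A probe at 8.2 in the control and 13.0 after treatment (log2 ratio 0.66) lay 2.17 robust SDs above them. Another, at 6.3 and 9.2 (log2 ratio 0.55), lay 1.68 above. The 10 brightest control probes had ratios of treated over control from 0.943 to 1.52, with 7 above 1 and 3 below.

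**Figure D1:**
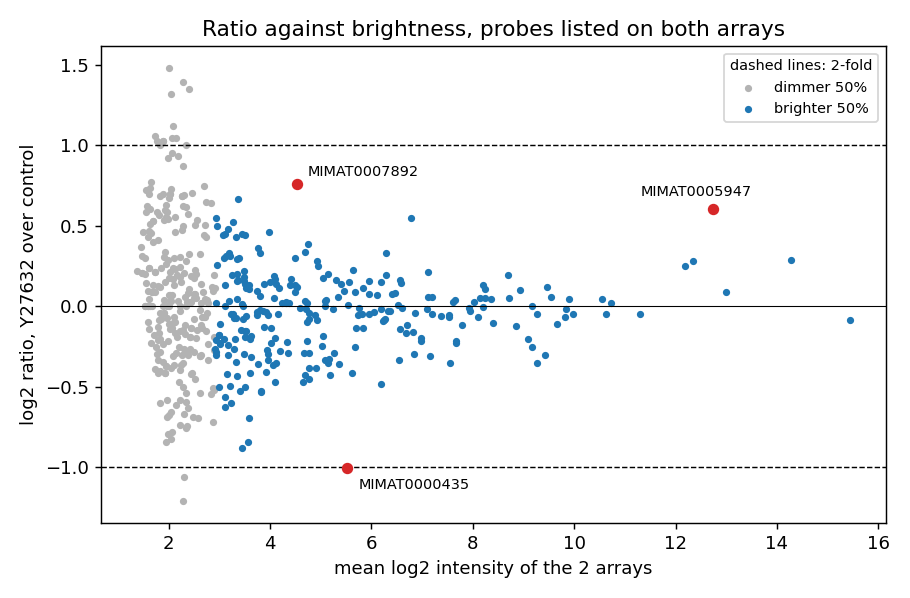
Log2 ratio of the Y27632 over the control array (vertical axis) against mean log2 intensity (horizontal axis) for the 519 probes listed on both arrays. Points are probes, grey in the dimmer 50% and blue in the brighter 50%. Red marks the 3 probes listed on both arrays that the text names, and dashed lines mark 2-fold. The cloud narrows with brightness, and in the brighter 50% only MIMAT0000435 reaches a dashed line.

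The spread of ratios was larger among dim than among bright probes. In the dimmest 25% (130 probes, geometric mean 2.59 to 4.30) the SD of log2 ratios was 0.47, and in the brightest 25% (130 probes, 26.2 and above) it was 0.21. Among the 259 dimmer probes, 13 were at least 2-fold higher after Y27632 and 2 were at least 2-fold lower. The lowest listed intensity was 2.3 on the control array and 2.7 on the Y27632 array, so the arrays also differed at their lower end. With the Y27632 values lowered by that difference of 0.4, 5 of the dimmer probes were at least 2-fold higher and 5 at least 2-fold lower.

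MiRNAs listed on 1 array only were almost all dim. The median intensity was 3.2 for the 100 control-only probes and 3.7 for the 95 Y27632-only probes, against 7.7 and 7.6 on the same arrays for probes listed on both. The highest Y27632-only intensity was 7.4. The highest control-only intensity, 15.3, belonged to MIMAT0002868, and the next was 6.5. MIMAT0002868 was chosen after its values were seen. All 82 other probes within 1.5-fold of its control intensity (10.3 to 22.5) were listed on the Y27632 array, at intensities from 7.0 to 30.2. No fold is given, because what a missing value stands for is not stated in the sources used here.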

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

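Of the tests in this part, those on missing replicates, missing values, the lowering of the Y27632 values by 0.4, the limit of 3 robust SDs and the distances of single probes after lowess and quantile normalization were chosen only after the result was seen.

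The 95 miRNA probes with a value on the Y27632 array and none on the control array were outside the ratio comparison. They drew attention as signal without a control counterpart. A detection limit near the lowest listed values is consistent with most of these and with the 100 control-only probes. Of 441 values of 10 or more on either array, 0.227% had no value on the other, which is the single probe MIMAT0002868. That probe remains open, since a rejected spot and a loss of signal after Y27632 would both leave the cell empty.

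Among the 259 dimmer probes, 13 were at least 2-fold higher and 2 at least 2-fold lower after Y27632. After the Y27632 values were lowered by 0.4, the difference between the lowest listed intensities, 5 were higher and 5 lower, so a higher floor on the Y27632 array may account for the excess of higher values. A response to Y27632 among dim miRNAs cannot be told apart from a higher floor with 1 array per condition.

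In the brighter 50%, 3 probes lay more than 3 robust SDs from the 100 probes nearest in brightness. MIMAT0000435 was at −4.32 robust SDs after a lowess correction and at −4.66 after quantile normalization. A further probe, at 91.5 in the control and 133.6 after Y27632 (log2 ratio 0.55), was at 3.58 as deposited, 3.55 after lowess and 3.30 after quantile normalization. MIMAT0005947 was at 4.48 as deposited, 3.35 after lowess and 2.32 after quantile normalization (log2 ratio 0.26). Its 100 neighbours ran from 40.7 to 44494.5 with 3 of them brighter, so a trend among the brightest probes stays open for it. The probes ranked 2 and 5 in control brightness also rose, at 2.21 and 2.14 robust SDs as deposited. Those ranked 1 and 3 lay at −0.49 and 0.76. For all 3 probes beyond 3 robust SDs, a spot artefact and a response to Y27632 stay open with 1 array per condition. So does a difference in vehicle or time of harvest, which the control's title does not state. These 3 probes are also the extremes of 260 under a limit set after seeing the data, so ordinary variation between arrays stays open too.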

How the results depend on the processing

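In the brighter 50%, 0 probes were at least 2-fold higher and 1 lower, and the counts were also 0 and 1 in the brightest 25%. Median centring moved no value, since the median log2 ratio was already 0.00, and so says nothing about stability. Quantile normalization, the lowess correction and the pseudocount each left 0 higher and 0 lower, because the ratio of MIMAT0000435 sits at the limit (−1.002) and moved to between −0.96 and −0.94. Without a filter on dim probes the counts were 13 higher and 3 lower. A 1.5-fold limit gave 3 higher and 6 lower. Missing values set to the lowest listed gave 3 higher and 4 lower, but the brighter 50% then held 357 probes and reached dimmer ones. Of those 7 probes, 5 were dim probes listed on both arrays with unchanged ratios, 1 was MIMAT0000435, and 1 (MIMAT0002868) had a filled value. Of the alternatives added after seeing the data, lowering the Y27632 values by 0.4 with no filter gave 5 higher and 6 lower, no filter with a 1.5-fold limit gave 46 higher and 28 lower, and a limit of 3 robust SDs gave 2 higher and 1 lower. The median log2 ratio was 0.00 over all probes, −0.03 in the brighter 50% (−0.031) and −0.03 in the brightest 25% (−0.028). For the 6 probes picked by ratio under the fixed rule, all 18 values under quantile normalization, lowess and the pseudocount kept their direction. The 15 that kept their side of the 2-fold limit started short of it, which says little about stability. Other settings for the miRNA lists were not run, because the accessions could not be paired with names. No replicate could be left out. No paired analysis was possible because each condition has 1 array. Low intensity limits the dimmer 50% most, and signal over background could not be examined.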

Other observations

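The brightest probes sat in the highest-numbered block of accessions. MiRBase numbers mature sequences broadly in order of registration. With the 1001 probes split into 4 groups of near-equal size by accession number, all 11 control probes above 1000 fell in the highest-numbered group, including the maximum of 45829.6. The brightest control probe of the lowest-numbered group read 935.0, and the maxima of the groups between were 143.7 and 296.9. The 41 probes numbered above the last of the 11 reached at most 474.1 in the control.

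Probes of intermediate brightness were distributed differently. Of the 48 probes above 100 on both arrays and at most 1000 in the control, 36 were in the lowest-numbered group, 3 in each of the groups between and 6 in the highest. The share of probes listed on both arrays was 64.9%, 35.2%, 46.8% and 60.4% from the lowest-numbered to the highest-numbered group. Median control intensity of those probes was 18.1, 5.35, 6.9 and 6.8 in the same order. Median log2 ratios of Y27632 over control were −0.02, −0.01, 0.00 and 0.04. No explanation for the brightness of the highest-numbered accessions was tested, since probe sequences were not used here.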
